A study of Mus musculus with 40 samples.

How the data were processed

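The study measured gene expression by RNA sequencing of polyadenylated RNA from the forebrain of mouse embryos. It compared wild-type (WT) mice with mice carrying an added copy of Chd8 (KI, the name in the labels), at embryonic days 14.5 and 18.5 (E14.5 and E18.5). Per the labels there are 5 WT and 5 KI libraries at each stage, each from the forebrain of a male mouse. The labels do not say whether the libraries of a group came from separate litters, so the authors' p-values per gene measure the spread between these libraries. The tests of gene lists and of positions described below compare genes with other genes. Their p-values do not measure the spread between libraries. The series also has CHD8 chromatin immunoprecipitation and input libraries (3 per genotype each) and ATAC-seq libraries (4 per genotype) at E14.5, which were not analysed here.

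Per the submitters' processing notes, the tools named for the series include Trimmomatic 0.39, HISAT2 2.1.0, featureCounts 2.0.0 and DESeq2 1.26.0, with the mm10 genome build. The values used here are the authors' own comparison of KI with WT, 1 table per stage, which the authors made with DESeq2 per the submitters' processing notes. Per the file headers each table gives, for every gene, a mean normalized count, a log2 fold change, the standard error (SE) of that log2 fold change, a score (the Wald statistic), a p-value and an adjusted p-value. The deposited score equals the deposited log2 fold change divided by its SE, and the deposited adjusted p equals the Benjamini-Hochberg adjustment over the genes that have one. The mean normalized count is the authors' mean over the libraries of a stage, so it is given without SD or n. The tables used here hold no column per library (0 columns of per-sample values), so no total count per library was known. The depth per library and the spread between single libraries are therefore unknown here, and precision is given by the authors' SE.

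The headers do not state which genotype is the numerator. The direction was read from Chd8, which must be raised by an added copy and is positive at both stages, so Chd8 is not an independent check of the labels. A positive log2 fold change is read as higher in KI throughout.

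Genes are listed by NCBI gene ID. Symbols and coordinates were taken from a RefSeq gene table of assembly GRCm38.p6, the assembly of the mm10 build. At E14.5, 17192 of 17940 IDs matched (95.8%) and 748 did not; at E18.5, 15064 of 15449 matched (97.5%) and 385 did not. The lowest mean normalized count in the table is 0.987 at E14.5 and 9.70 at E18.5, so the 2 tables were filtered differently before they were deposited. An adjusted p is present for 13417 genes at E14.5 and 13601 at E18.5, with lowest mean normalized counts of 25.2 and 32.7. Genes without one stay out of every count and list test.

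The following were fixed before the data were examined: the tests, the alternatives, the 44 gene lists and the rule for named genes. The plan was a count model on values per library, with this fallback for tables that hold only the authors' result, and the fallback was used. A gene is called changed when its deposited adjusted p is under 0.05, with no fold threshold. Named genes are Chd8, then per stage the 10 highest and 10 lowest log2 fold changes among called genes with a mean normalized count of at least 50. From each list the rule adds up to 4 called members and the first 2 genes as written, and it adds the 5 genes with the lowest adjusted p for the difference between stages. Symbols of the form Gm or Rik and pseudogene symbols ending in -ps are left out; pseudogenes with other symbols are not. The rule gave 121 genes besides the stage-difference genes that it did not already name; any gene named outside it is said to have been chosen after its values were seen. Results of a few genes that the rule or the lists would name are not reported here.

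The 44 lists were written from general knowledge. They cover cell types (radial glia, intermediate progenitors, neurons of several classes, glia, microglia, endothelium, meninges, choroid plexus, erythroid cells and tissue outside the forebrain) and processes (cell cycle, synapse, ion channels, axon guidance, chromatin, metabolism, stress and interferon responses). Others are the CHD family, Wnt and p53 targets, REST targets, high-confidence autism genes, the neighbours of Chd8, Hox genes, mitochondrially encoded genes and a sex-linked check. Some genes stand in more than 1 list. Each list with at least 5 measured members was tested with cameraPR of limma 3.58.1 (R 4.3.3) on the deposited Wald statistic. The test is competitive, comparing members with all other genes, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 39 lists tested at a stage. A correlation cannot be estimated without values per library, so each test was repeated with a correlation of 0.05. "Adjusted over the list alone" means that the deposited p-values were adjusted over the list's measured members only.

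The KI effect here means the difference between the KI and WT libraries of a stage, whatever its cause. The KI effect at E18.5 was compared with that at E14.5 per gene. The statistic was the difference of the deposited log2 fold changes divided by the root of the summed squared SEs. The p is 2-sided, from a normal distribution, and adjusted over the 13106 genes tested at both stages. The stages share no libraries. For lists, cameraPR was run on that statistic for the 37 lists with at least 5 measured members. Correlations across genes have a jackknife SE, from leaving out each chromosome in turn. That SE holds no spread between libraries, so it does not cover a difference that shifts genes of every chromosome together. Genes are not independent replicates, so no p is given. The positions of called genes were tested by Fisher's exact test per chromosome, adjusted over chromosomes, and within 5 Mb of Chd8. Fisher's exact test treats genes as independent, which genes that vary together are not. Position, correlation and counts were computed in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

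The alternatives tried were other sets of genes for the adjustment, the Benjamini-Yekutieli adjustment, an empirical null (centre and scale from the median and the median absolute deviation of the Wald statistics), other thresholds, other set-test settings and other windows. The steps were tested on simulated data. With the deposited SEs at 13106 genes, a change of 0.15 log2 was recovered in 17.1% of changed genes at E14.5 and 16% at E18.5, one of 0.25 in 55.4% and 50.1%, and one of 0.5 in 86.2% and 86.6%. For the difference between stages these shares were 4.03%, 23.8% and 68.5%. Of simulated lists of 20 genes among 13417 genes, 0.333% of unchanged lists and 100% of lists shifted by 0.1 log2 were called. Noise was drawn independently for each gene, so these shares do not cover lists whose members vary together. The simulated Wald statistics also lack the scale of 1.22 that the deposited ones have at E14.5.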

Results

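The data are the authors' deposited comparisons of KI with WT forebrain, 5 libraries against 5 at E14.5 and again at E18.5. CHD8 is an ATP-dependent chromatin remodeler whose gene is among those most often mutated in autism, and the study's title asks what an extra copy does to brain development and behaviour. E14.5 falls within the period of cortical neurogenesis and E18.5 shortly before birth. The authors' deposited table gives a median SE of the log2 fold change of 0.068 over the genes tested at E14.5 and 0.073 at E18.5, for median mean normalized counts of 615 and 641.

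Chd8 itself was higher in KI at both stages. In the authors' deposited table its log2 fold change was 0.64 (SE 0.031, adjusted p = 1.49e-88) at E14.5, 55.8% above WT, at a mean normalized count of 6900. At E18.5 it was 0.51 (SE 0.038, adjusted p = 1.34e-37) in the authors' deposited table, at a mean normalized count of 6202. The gene (NCBI gene ID 67772) lies on chromosome 14 at 52198151 to 52258042 in GRCm38. Its change at E18.5 minus that at E14.5 was −0.13 (SE 0.049, 95% interval −0.22 to −0.03), which did not pass over all genes (adjusted p = 0.999). Of the other 8 members of the CHD family none passed over all genes at either stage, among them Chd7, the gene altered in CHARGE syndrome, at 0.16 (SE 0.050, adjusted p = 0.0835) at E14.5 and 0.00 (SE 0.059) at E18.5 in the authors' deposited table. Adjusted over the list alone, 4 of the 9 members rose at E14.5 (Chd3, Chd6, Chd7 and Chd8) and 2 at E18.5 (Chd3 and Chd8). The family as a list was higher at E14.5 (cameraPR adjusted p = 5.2e-13, and 0.016 without Chd8) and at E18.5 (adjusted p = 6.76e-07), where the call ended without Chd8 (adjusted p = 0.240), with ranks (adjusted p = 0.253) and with log2 fold changes as the statistic (adjusted p = 0.140).

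The comparison at E14.5 asked which genes of the mid-gestation forebrain differ when Chd8 is duplicated. Of 13417 genes tested, 162 were called changed, 99 higher and 63 lower in KI. The largest rises after the gene rule were those of Car14, a membrane-bound carbonic anhydrase, at 0.82 (SE 0.119, adjusted p = 1.99e-08), and of H2-K1, a class I histocompatibility gene, at 0.79 (SE 0.146, adjusted p = 4.8e-05), in the authors' deposited table. The largest falls were those of Zcwpw1, a histone reader used in meiosis, at −0.59 (SE 0.134, adjusted p = 0.00277), and BC025920, annotated as a transcribed pseudogene, at −0.54 (SE 0.103, adjusted p = 0.000133), in the authors' deposited table. Most changes were small: the called genes had a median absolute log2 fold change of 0.257, 19 of them reached 0.5 and 2 reached 1.

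Further rises in the authors' deposited table were H2-Q4, another class I histocompatibility gene, at 0.71 (SE 0.181, adjusted p = 0.0132), and Phf19, a Polycomb-like protein, at 0.67 (SE 0.107, adjusted p = 5.89e-07). The metallothionein gene Mt1 stood at 0.66 (SE 0.111, adjusted p = 4.91e-06) and Dmrta1, a transcription factor of dorsal telencephalic progenitors, at 0.64 (SE 0.142, adjusted p = 0.00205), in the authors' deposited table. Gsta4 (a glutathione S-transferase), Plekhg4 (a pleckstrin-homology domain protein) and Ermn (an oligodendrocyte cytoskeletal protein) were at 0.64, 0.62 and 0.61 (SE 0.154, 0.163 and 0.160; adjusted p = 0.00704, 0.0169 and 0.0169) in the authors' deposited table. Among the falls, the authors' deposited table gives −0.51 (SE 0.143, adjusted p = 0.0325) for Crlf2, the receptor of thymic stromal lymphopoietin, and −0.49 (SE 0.137, adjusted p = 0.0315) for Ndnf, a secreted factor of layer 1 neurons. Lyrm7, an assembly factor of respiratory complex III, and Cradd, a death-domain adaptor, fell to −0.48 and −0.47 (SE 0.123 and 0.126, adjusted p = 0.0130 and 0.0213) in the authors' deposited table. Nsmce1, a subunit of the SMC5/6 complex, had the lowest adjusted p of the falls named here (−0.42, SE 0.065, adjusted p = 1.75e-07, in the authors' deposited table). Wdpcp, a cilium gene, Mc4r, the melanocortin 4 receptor, and Dync1i1, a neuronal dynein chain, each stood at −0.38 (SE 0.109, 0.103 and 0.082; adjusted p = 0.0399, 0.0260 and 0.00167) in the authors' deposited table.

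**Figure D1:**
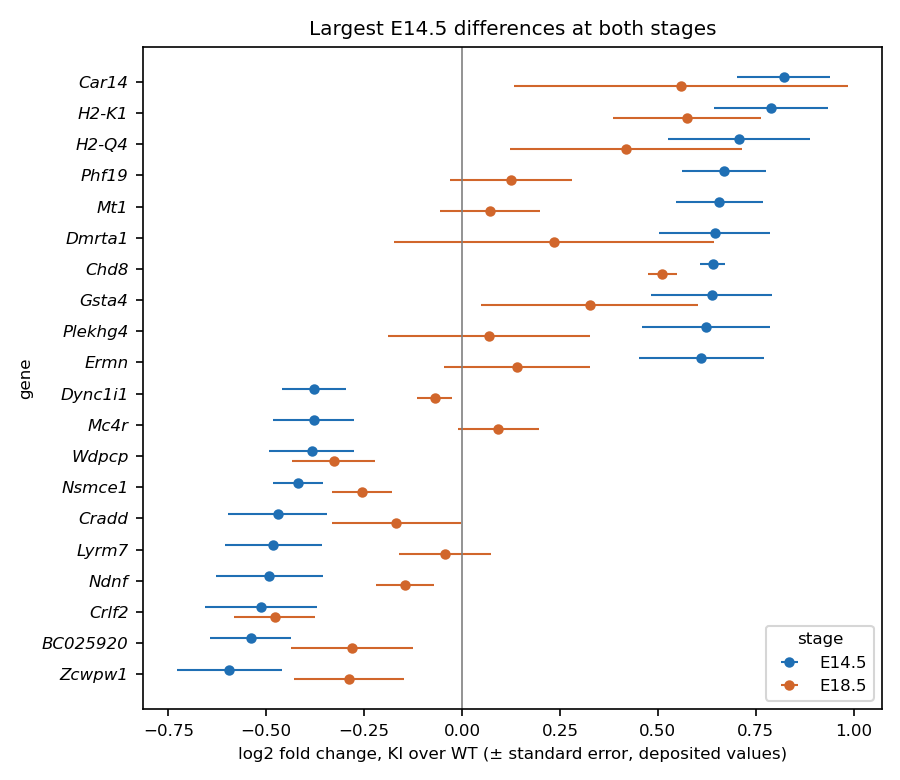
Log2 fold change of KI over WT (x axis) for the 10 highest and 10 lowest called genes of E14.5 with a mean normalized count of at least 50 (y axis), with the authors' standard errors as bars, at E14.5 (blue) and E18.5 (orange). Car14 is the highest gene shown at 0.82 and Zcwpw1 the lowest at −0.59 at E14.5; at E18.5 Chd8 and Crlf2 are the genes shown that passed.

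With the empirical null, 31 genes passed at E14.5 in place of 162, of which 80.65% were higher in KI against 61.11%; the Wald statistics had a scale of 1.22. Pkm, Pfkl, Ldha, Tpi1, Neurod6, Ldb2, Dlx1, H2-D1, Crlf2, Zcwpw1 and Ndnf are among the named genes whose call ended there.

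Among the gene lists at E14.5, markers of deep-layer projection neurons were lower in KI as a group. These are the corticofugal neurons made first in the cortex, and 19 of the 20 measured members were below 0, with a median log2 fold change of −0.12 (cameraPR adjusted p = 4.04e-08; adjusted p = 3.67e-05 with a correlation of 0.05). Ldb2, a LIM-domain cofactor, fell at −0.25 (SE 0.071, adjusted p = 0.0438), while Tbr1, a master regulator of layer 6, was at −0.12 (SE 0.045, adjusted p = 0.209) and Bcl11b at −0.03 (SE 0.052, adjusted p = 0.888) in the authors' deposited table. Over all genes 1 member fell; adjusted over the list alone 9 fell (Cdh13, Ldb2, Nfib, Sox5, Tbr1, Zfpm2, Syt6, Fezf2 and Hs3st4). Pan-neuronal genes were lower by less, with 17 of 20 below 0 and a median of −0.04 (cameraPR adjusted p = 0.00755), a call lost at a correlation of 0.05 (adjusted p = 0.0712). Neurod6, a transcription factor of excitatory cortical neurons, fell at −0.20 (SE 0.046, adjusted p = 0.00438) in the authors' deposited table. The widely used markers Tubb3 and Dcx stood at −0.03 and −0.03 (SE 0.038 and 0.031, adjusted p = 0.831 and 0.791) in the authors' deposited table. Adjusted over the list alone, Neurod6, Neurod2 and Cntn2 fell and Nefm rose. GABA and glycine receptor genes were also lower (12 of 15 below 0, median −0.10, cameraPR adjusted p = 0.00755), again lost at a correlation of 0.05 (adjusted p = 0.0623); none of them passed singly, over all genes or adjusted over the list alone.

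Hypoxia and glycolysis genes were higher, with 19 of 22 members above 0 and a median of 0.10 (cameraPR adjusted p = 5.05e-06; adjusted p = 0.000891 with a correlation of 0.05). The glycolytic enzyme genes Pfkl, Tpi1, Ldha and Pkm rose at 0.23, 0.20, 0.18 and 0.17 (SE 0.051, 0.047, 0.043 and 0.042; adjusted p = 0.00284, 0.00348, 0.0074 and 0.0063) in the authors' deposited table. Vegfa stood at 0.20 (SE 0.069, adjusted p = 0.143) and Bnip3, a hypoxia target outside glycolysis, at 0.00 (SE 0.074, adjusted p = 0.996) in the authors' deposited table. Over all genes 4 rose, and adjusted over the list alone 6, the others being Gapdh and Vegfa.

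Interferon response genes were higher (6 of 7 above 0, median 0.25, cameraPR adjusted p = 2.78e-05; adjusted p = 0.000277 with a correlation of 0.05). The members that rose over all genes, H2-K1 and H2-D1 (0.39, SE 0.094, adjusted p = 0.00678, in the authors' deposited table), are class I histocompatibility genes rather than antiviral effectors, and their reads can be shared with close paralogs. Adjusted over the list alone 4 rose, with B2m and Ifit2 added; Ifit2 stood at 0.29 (SE 0.087, adjusted p = 0.0656) in the authors' deposited table.

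Markers of the GABAergic interneuron lineage were higher (17 of 23 above 0, median 0.08, cameraPR adjusted p = 0.00766), a call lost at a correlation of 0.05 (adjusted p = 0.0712). Dlx1, a ventral forebrain homeobox gene, rose at 0.17 (SE 0.047, adjusted p = 0.0369), and the GABA-synthesis genes Gad1 and Gad2 were at 0.08 and 0.08 (SE 0.065 and 0.057, adjusted p = 0.711 and 0.624) in the authors' deposited table. Dlx1, Dlx2, Nkx2-1 and Dlx6os1 rose adjusted over the list alone. Progenitor and division lists leaned upwards too: radial glia (16 of 25 above 0, median 0.03, cameraPR adjusted p = 0.0174; adjusted p = 0.112 with a correlation of 0.05) and G2/M genes (26 of 30 above 0, median 0.05, adjusted p = 0.0072; adjusted p = 0.0712 with a correlation of 0.05). Ttyh1 rose at 0.13 (SE 0.037, adjusted p = 0.0491), and Sox2 and Pax6 were at 0.16 and −0.01 (SE 0.060 and 0.042, adjusted p = 0.194 and 0.963) in the authors' deposited table; adjusted over the list alone Hes1, Id4 and Ttyh1 rose. No G2/M gene passed singly, over all genes or adjusted over the list alone, and Mki67 stood at 0.03 (SE 0.046, adjusted p = 0.844) in the authors' deposited table. Cytosolic ribosomal protein genes were higher (29 of 39 above 0, median 0.04, cameraPR adjusted p = 0.00734; adjusted p = 0.0943 with a correlation of 0.05). Of these Rps27 rose adjusted over the list alone.

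Lists of other tissues were also higher at E14.5. Erythroid genes were higher in all 6 members measured at E14.5 (median 0.52, cameraPR adjusted p = 1.26e-07; adjusted p = 2.84e-06 with a correlation of 0.05). The embryonic globins Hbb-y and Hba-x rose at 0.50 and 0.59 (SE 0.068 and 0.149, adjusted p = 1.64e-09 and 0.0118), and the adult globin Hba-a1 stood at 0.45 (SE 0.385, adjusted p = 0.720), in the authors' deposited table. The same 2 genes rose adjusted over the list alone, and globins were 0.0153% of the summed mean normalized counts. Markers of meninges and fibroblasts were higher in 8 of 10 members (median 0.23, cameraPR adjusted p = 0.0204), with Col1a2 at 0.61 (SE 0.207, adjusted p = 0.118) in the authors' deposited table as the gene that passed adjusted over the list alone. That call was lost at a correlation of 0.05 (adjusted p = 0.0712), at a mean normalized count of at least 50 (adjusted p = 0.0901) and without chromosome 6 (adjusted p = 0.0891).

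The other lists tested at E14.5 did not pass. Their cameraPR adjusted p was 0.0798 for glutamate receptors and postsynapse, 0.0893 for Wnt targets, ribosome biogenesis and p53 targets alike, 0.130 for extracellular matrix and for chromatin remodelers, and 0.158 for the unfolded protein response. It was 0.218 for the neighbours of Chd8, 0.240 for G1/S genes, 0.290 for diencephalon markers, REST targets and nuclear-encoded mitochondrial respiration, 0.396 for upper-layer neurons and 0.427 for protocadherins. It was 0.499 for axon guidance and for intermediate progenitors, 0.522 for microglia, 0.616 for endothelium and for the astrocyte lineage, and 0.636 for immediate early genes. It was 0.855 for synaptic vesicle genes, the oligodendrocyte lineage, Cajal-Retzius cells and autism genes, 0.899 for striatal neurons, 0.911 for cholesterol biosynthesis and 0.969 for voltage-gated channels. Single members of these lists did pass over all genes in the authors' deposited table: the cell cycle gene Ccnd1 (0.18, SE 0.046), the upper-layer gene Cux1 (0.18, SE 0.043), the stress regulator Atf4 (0.16, SE 0.046), the guidance cue Ntn1 (0.25, SE 0.062) and the release-site gene Rims2 (0.23, SE 0.066) rose. The Slit receptor Robo2 (−0.13, SE 0.035), Fosl2 (−0.34, SE 0.093) and Pcdhga12 (−0.34, SE 0.091) fell in the authors' deposited table, and Ndnf is the member of the Cajal-Retzius list. Adjusted over the list alone, Axin2, Ccnd1, Pmaip1, Fn1, Nid2, Ino80, Psat1, Atf4, Nefm, Cux1, Pcdhga9, Efnb3, Ntn1, Rims2, Apoe and Fgfr3 rose. In the same lists Gdap1, Pcdhac2, Pcdhga12, Robo2, Fosl2 and Ndnf fell adjusted over the list alone.

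At E18.5 the comparison was repeated just before birth. Of 13601 genes tested, 9 were called changed, 6 higher and 3 lower in KI. Besides Chd8, the rises in the authors' deposited table were Marchf8, a membrane-bound ubiquitin ligase (0.21, SE 0.039, adjusted p = 0.000386), Pkm (0.14, SE 0.030, adjusted p = 0.00841), Pfkl (0.20, SE 0.047, adjusted p = 0.0299) and Pcdhga11, a clustered protocadherin (0.28, SE 0.064, adjusted p = 0.0165). A gene with no matching symbol (ID 100504526), chosen after its values were seen, rose at 0.64 (SE 0.118, adjusted p = 0.00031) in the authors' deposited table. The falls in the authors' deposited table were Crlf2 (−0.48, SE 0.103, adjusted p = 0.00854), the ESCRT-III gene Chmp2a (−0.31, SE 0.057, adjusted p = 0.000258) and Mpst, a sulfurtransferase (−0.23, SE 0.055, adjusted p = 0.0391). With the empirical null 19 genes passed at E18.5, with genes of mean normalized count of at least 100 alone 14, and with the Benjamini-Yekutieli adjustment 4.

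As groups, genes of cell division were lower in KI at E18.5. G2/M genes were below 0 in 28 of 30 members (median −0.09, cameraPR adjusted p = 1.03e-05; adjusted p = 0.00289 with a correlation of 0.05), and G1/S genes in 25 of 30 (median −0.10, adjusted p = 3.55e-05; adjusted p = 0.00538 with a correlation of 0.05). None of these genes passed over all genes. Adjusted over the list alone the proliferation marker Mki67 fell, at −0.17 (SE 0.052, adjusted p over all genes = 0.266) in the authors' deposited table, while Top2a stood at −0.09 and the replication helicase genes Mcm2 and Mcm3 at −0.05 and −0.10 (SE 0.066, 0.080 and 0.085). Radial glia markers were lower (18 of 25 below 0, median −0.06, cameraPR adjusted p = 0.00555), a call lost at a correlation of 0.05 (adjusted p = 0.0622), with no member passing over all genes or adjusted over the list alone. The oligodendrocyte lineage was lower (12 of 16 below 0, median −0.05, cameraPR adjusted p = 0.00463; adjusted p = 0.0334 with a correlation of 0.05). The call was lost with ranks (adjusted p = 0.0629). Of its members Olig1 and Olig2, early lineage transcription factors, were at −0.22 and −0.19 (SE 0.060 and 0.072, adjusted p = 0.141 and 0.598) in the authors' deposited table, and adjusted over the list alone Olig1, Olig2 and Ugt8a fell.

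Several groups were higher at E18.5. Hypoxia and glycolysis genes were above 0 in 19 of 23 members (median 0.09, cameraPR adjusted p = 3.98e-09; adjusted p = 2.5e-05 with a correlation of 0.05); Pfkl and Pkm rose over all genes, and Tpi1 also adjusted over the list alone. The GABAergic interneuron lineage was above 0 in 20 of 23 (median 0.09, cameraPR adjusted p = 1.03e-05; adjusted p = 0.00218 with a correlation of 0.05). Gad1 and Gad2 were at 0.15 and 0.12 (SE 0.066 and 0.051, adjusted p = 0.770 and 0.743) in the authors' deposited table, and Slc32a1, the vesicular GABA transporter, rose adjusted over the list alone. Interferon response genes were above 0 in 11 of 13 (median 0.24, cameraPR adjusted p = 0.000133; adjusted p = 0.00289 with a correlation of 0.05), and adjusted over the list alone H2-D1, H2-K1 and Ifit2 rose. Cytosolic ribosomal protein genes were above 0 in 33 of 39 (median 0.04, cameraPR adjusted p = 1.17e-06; adjusted p = 0.00218 with a correlation of 0.05). That call was lost with log2 fold changes as the statistic (adjusted p = 0.0553). Rps27 and Rplp2 passed adjusted over the list alone. Pan-neuronal genes were above 0 in 16 of 20 (median 0.03, cameraPR adjusted p = 0.00152; adjusted p = 0.0210 with a correlation of 0.05). This call too was lost with log2 fold changes (adjusted p = 0.332). Markers of diencephalon, hypothalamus and midbrain were above 0 in 5 of 5 (median 0.21, cameraPR adjusted p = 0.00312; adjusted p = 0.008 with a correlation of 0.05). At a mean normalized count of at least 50 under 5 members were left and the list could not be tested. Of these members Gbx2, a thalamic homeobox gene, stood at 0.70 (SE 0.224, adjusted p = 0.347) in the authors' deposited table and passed adjusted over the list alone.

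**Figure D2:**
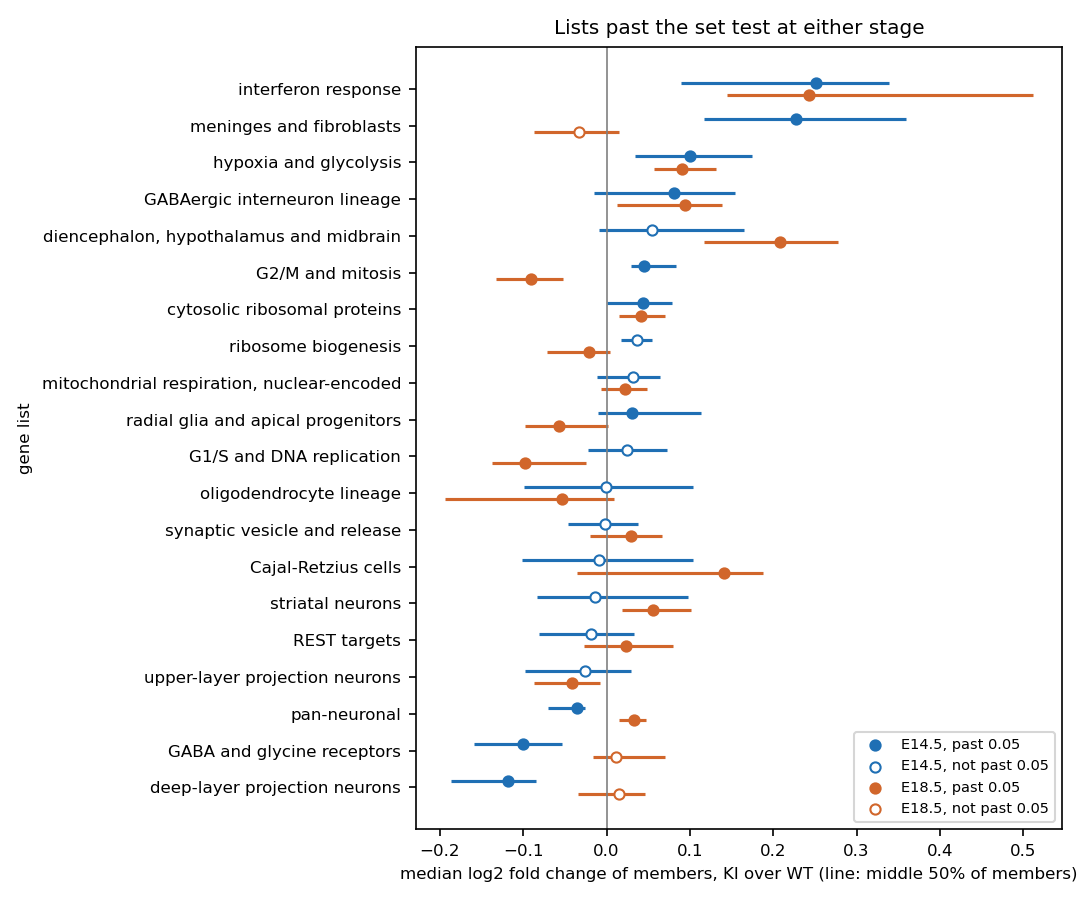
Median log2 fold change of KI over WT (x axis) over the measured members of each of the 20 lists drawn (y axis), at E14.5 (blue) and E18.5 (orange), with lines over the middle 50% of members and filled points where cameraPR passed 0.05. Deep-layer neurons are at −0.12 at E14.5 and 0.01 at E18.5, and G2/M genes at 0.05 and −0.09; the CHD family and erythroid lists, which also passed, are not drawn.

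The remaining lists past the test at E18.5 lost their call at a correlation of 0.05. Higher were synaptic vesicle genes (cameraPR adjusted p = 0.0138; 0.0914 as the adjusted p at a correlation of 0.05), striatal neurons (adjusted p = 0.0153, then 0.0914), REST targets (adjusted p = 0.0208, then 0.125), Cajal-Retzius cells (adjusted p = 0.0411, then 0.112) and nuclear-encoded mitochondrial respiration (adjusted p = 0.0460, then 0.209). Lower were ribosome biogenesis (adjusted p = 0.0165, then 0.108) and upper-layer neurons (adjusted p = 0.0441, then 0.144). No member of these lists passed over all genes, and adjusted over the list alone Car10 of the Cajal-Retzius list rose. The members of that list were split, with 7 of 12 above 0 and 5 below. Cux2, a transcription factor of upper-layer neurons, was at 0.00 (SE 0.064) in the authors' deposited table.

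The other lists did not pass at E18.5. Their cameraPR adjusted p was 0.0759 for voltage-gated channels, 0.0964 for Wnt targets, intermediate progenitors and endothelium, 0.122 for the astrocyte lineage and for glutamate receptors, and 0.136 for axon guidance. It was 0.195 for GABA and glycine receptors, 0.199 for microglia, the unfolded protein response and the neighbours of Chd8, 0.432 for cholesterol biosynthesis, 0.680 for choroid plexus and 0.819 for protocadherins and for meninges. The choroid plexus and meninges tests rest on 7 and 5 measured members. A further 6 and 11 members have no p at E18.5, among them Ttr, Col1a1 and Col1a2, so these tests do not cover them. It was 0.888 for extracellular matrix, p53 targets, immediate early genes, chromatin remodelers, deep-layer neurons and autism genes. Adjusted over the list alone the autism gene Setd5 fell and Pcdhga9 rose. Setd5 lies next to Gt(ROSA)26Sor on chromosome 6, a chromosome with frequent changes taken up further below. Fewer than 5 measured members kept the choroid plexus list (4 at E14.5), the erythroid list at E18.5 (3), the muscle, bone and skin list (3 and 4), the sex-linked check (4 at each stage), the Hox genes (0) and the mitochondrially encoded genes (0) from a test. In the muscle, bone and skin list at E14.5 Col2a1 and Sox9 rose and Krt10 fell adjusted over the list alone. That adjustment covered only 3 genes, and the rises were at most 0.115. Sox9 is also in the radial glia list, where it did not pass adjusted over the list alone. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y lay between −0.03 and 0.06 at E14.5 and between 0.03 and 0.13 at E18.5 in the authors' deposited table, with none called. Xist had a mean normalized count of 7.08 at E14.5.

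In some lists the median, the mean and the test differed in sign, 7 at E14.5 and 8 at E18.5, none of which passed. At E14.5 they were the astrocyte, oligodendrocyte, synaptic vesicle, autism, cholesterol, voltage-gated channel and immediate early lists. At E18.5 they were the deep-layer, protocadherin, extracellular matrix, immediate early, chromatin remodeler, p53, autism and choroid plexus lists.

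The design also asks whether the KI effect differs between the stages. Across the 13106 genes tested at both, the log2 fold changes had a Pearson r of 0.215 (jackknife SE 0.0161) and a Spearman rho of 0.216 (jackknife SE 0.00922). Of the 156 genes other than Chd8 called at E14.5 and tested at both stages, 131 had the same sign at E18.5 (84.0%, against 57.5% of genes not called). In size, 151 of the 156 were smaller at E18.5, a drop that selection on the E14.5 value also gives. The median went from 0.27 to 0.11 for the 93 higher genes among the 156 and from −0.24 to −0.07 for the 63 lower genes. All 8 genes other than Chd8 called at E18.5 had the same sign at E14.5. Besides Chd8, the genes called at both stages were Marchf8, Pkm and Pfkl, higher (3 against 0.0355 by chance, Fisher's exact test p = 3.42e-06), and Crlf2, lower (1 against 0.0144 by chance, Fisher's exact test p = 0.0144).

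**Figure D3:**
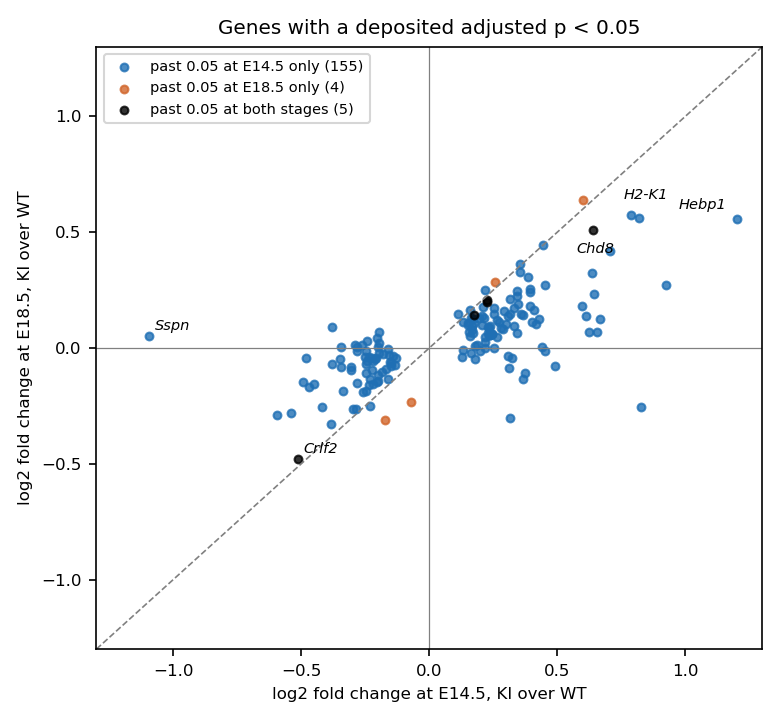
Log2 fold change of KI over WT at E14.5 (x axis) and at E18.5 (y axis) for the 164 genes with a deposited adjusted p under 0.05 at a stage and a value at both, with the dashed line marking equal values. Blue points (155) passed at E14.5, orange points (4) at E18.5 and black points (5) at both; most blue points lie nearer to 0 on the y axis than on the x axis.

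No single gene passed the test of the stage difference (0 of 13106 by the normal test on the deposited values, with 593 at an unadjusted p under 0.05, or 4.52%, and a lowest adjusted p of 0.350). The 5 genes nearest to passing were Pif1, a DNA helicase (0.31 at E14.5 and −0.30 at E18.5 in the authors' deposited table), Olig2 (0.23 and −0.19), Gnal (−0.20 and 0.04), Rabgap1l (−0.19 and 0.07) and Sspn (−1.09 and 0.05). Gene lists did differ between stages, 14 of the 37 tested, and 9 with a correlation of 0.05. The 5 lost there were REST targets (adjusted p = 0.0678), the oligodendrocyte lineage (adjusted p = 0.0562), Cajal-Retzius cells (adjusted p = 0.0873), and the neighbours of Chd8 and the CHD family (adjusted p = 0.0946 for both). The CHD family was tested here with Chd8 included. G2/M genes went from a median of 0.05 to −0.09 (cameraPR adjusted p of the difference = 1.06e-09; 5.0e-05 as the adjusted p at a correlation of 0.05) and deep-layer neurons from −0.12 to 0.01 (adjusted p of the difference = 3.34e-07; adjusted p = 0.0002 at a correlation of 0.05). For hypoxia and glycolysis, the GABAergic lineage and interferon response, which were higher at both stages, the adjusted p of the difference was 0.707, 0.463 and 0.363.

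**Figure D4:**
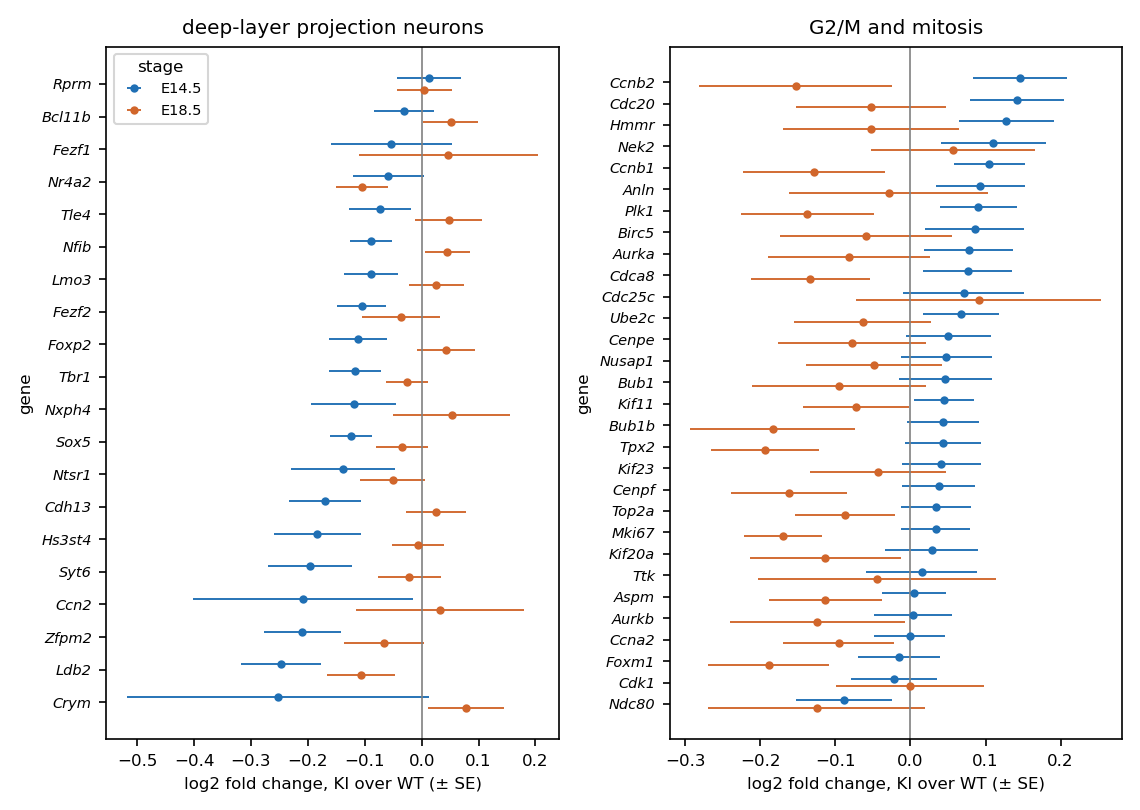
Log2 fold change of KI over WT (x axis) with the authors' standard errors as bars, for each measured gene (y axis) of the deep-layer neuron list (left) and the G2/M list (right), at E14.5 (blue) and E18.5 (orange). In the left panel 19 of 20 genes are below 0 at E14.5, and in the right panel 28 of 30 are below 0 at E18.5.

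The positions of changed genes were examined for segments carried along with the engineered locus. On chromosome 6, 18 of 640 tested genes were called at E14.5 (2.81% against 1.14% elsewhere, odds ratio 2.51, Fisher's exact test p = 0.00113, adjusted p = 0.0227), 9 higher and 9 lower. Among them are Neurod6, Ndnf, Dync1i1, Tpi1, Marchf8 and Sspn and, chosen after their values were seen, Chl1, Asb4, Hebp1 and Ift122. Genes of chromosome 6 with an unadjusted p under 0.05 were also more frequent at E14.5 (17.0% against 11.3%, adjusted p = 0.000562), as to a lesser degree were those of chromosome 7 (14.3% against 11.4%, adjusted p = 0.04998), while those of chromosome 5 were less frequent (8.54% against 11.8%, adjusted p = 0.0379). At E18.5 those of chromosome 6 were 8.81% against 5.88% (Fisher's exact test p = 0.00379, adjusted p = 0.0758). Within 5 Mb of Chd8 none of the 99 other genes was called at E14.5 and none of 100 at E18.5; at an unadjusted p under 0.05 there were 15 and 8 (Fisher's exact test p = 0.269 and 0.394).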

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

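Of the tests weighed in this part, those on precision, on globin share, on ventral forebrain, on genes beside Chd8, on chromosome 6 and on Gt(ROSA)26Sor were chosen only after the result was seen.

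14 gene lists stand here because the KI effect on them differed between E14.5 and E18.5 by a test of that difference (cameraPR, adjusted over 37 lists). The effect moved downwards from E14.5 to E18.5 for G2/M genes (adjusted p = 1.059e-09), G1/S genes (adjusted p = 2.073e-06), radial glia (adjusted p = 9.05e-06), ribosome biogenesis (adjusted p = 0.0001383), Wnt targets (adjusted p = 0.0008416), the oligodendrocyte lineage (adjusted p = 0.01128), the neighbours of Chd8 (adjusted p = 0.0319) and the CHD family (adjusted p = 0.04379). It moved upwards for deep-layer neurons (adjusted p = 3.34e-07), pan-neuronal genes (adjusted p = 1.397e-06), GABA and glycine receptors (adjusted p = 2.657e-05), glutamate receptors and postsynapse (adjusted p = 0.001702), REST targets (adjusted p = 0.005858) and Cajal-Retzius cells (adjusted p = 0.0295). With a correlation of 0.05 the adjusted p was 0.0678 for REST targets, 0.0562 for the oligodendrocyte lineage, 0.0873 for Cajal-Retzius cells, and 0.0946 for the neighbours of Chd8 and for the CHD family, while the other lists stayed past 0.05. The CHD family includes Chd8, whose own log2 fold change differed by −0.13 (SE 0.049). The test of the difference was not run without Chd8, so it does not show a change of the other members. The list medians at E14.5 and E18.5 were 0.02 and −0.10 for G1/S genes, 0.03 and −0.06 for radial glia, −0.04 and 0.03 for pan-neuronal genes, and −0.10 and 0.01 for GABA and glycine receptors.

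The first pattern weighed is that 162 genes passed at E14.5 and 9 at E18.5. Lower precision at E18.5 is argued against by the SEs in the authors' deposited tables, whose median ratio of E18.5 to E14.5 was 1.03, and different filtering of the tables by the genes with a mean normalized count of at least 100 in both, of which 150 passed at E14.5 and 8 at E18.5. For the 14 lists above the difference between KI and WT was not fully shared by the stages, 9 of them also with a correlation of 0.05. Whether genotype or another difference between the groups, such as the hour of collection, gave this cannot be told from the labels. For the single genes of the pattern, an effect that differs by stage cannot be told apart from a shared one. In the test of the difference 0 genes passed (593 at an unadjusted p under 0.05), and it recovers few small differences. A count of 0 had been set beforehand as the value against a stage-dependent effect, but that bound was wrong, because simulated stage differences of 0.15 and 0.25 log2 were recovered in 4.03% and 23.8% of genes. The wider Wald statistics at E14.5 (scale 1.22, against 0.949 at E18.5) leave open a difference between the E14.5 groups other than genotype, which was not tested for lack of values per library. With the empirical null, which takes out that scale, 31 genes passed at E14.5 and 19 at E18.5. The size of the gap between 162 and 9 therefore depends largely on the scale.

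The second pattern is that the KI difference at E14.5 runs against normal development. The developmental change is that of the mean normalized count from E14.5 to E18.5, relative to the median gene. It was taken over genes with a mean normalized count of at least 50 at both stages. Genes whose level at least doubled on that scale (1045 genes) had a median log2 fold change of −0.05 in KI at E14.5, with 64.2% below 0. Genes whose level at least halved (615) had one of 0.06, with 25.7% below 0. KI forebrains that were younger or less mature at E14.5 are a candidate explanation: the Spearman correlation of the KI effect with the developmental change was −0.1963 (jackknife SE 0.0126, 12278 genes), −0.271 at a mean normalized count of at least 1000 and −0.137 with the WT level in place of the mean of both genotypes. At E18.5 that correlation was 0.0758 (jackknife SE 0.0106), and 0.0340 at a mean normalized count of at least 1000. At E18.5 the genes whose level at least halved had a median of −0.04 in KI, with 62.4% below 0. Those whose level at least doubled had one of 0.01, with 47.0% below 0. The E18.5 values do not run in the direction of a lag of KI. Whether a lag lasts to E18.5 is not decided by them. No value had been set beforehand for E18.5, and the jackknife SEs of both stages hold no spread between libraries. A difference of hours in collection and a slower maturation at E14.5 caused by Chd8 would both give the E14.5 values, and the labels hold nothing that separates them.

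Other sources of that second pattern were tested as well. More blood in the E14.5 KI samples cannot be told apart from younger blood: the median of embryonic globins exceeded that of adult globins by 0.1436 (approximate SE 0.3712), and the few adult globins measured with wide SEs keep it open. Blood as the source of the trend across all genes is argued against by the globin share, 0.01529% of the summed mean normalized counts, with the limit that reads of adult globin paralogs can be shared and lost. For more ventral forebrain in KI samples, the median of the striatal list lay 0.0942 below that of the GABAergic list (difference −0.0942, bootstrap SE 0.04535). That narrowly met the value set against this explanation. It cannot decide, since other neuron lists were also lower at E14.5, which could hide a striatal rise. At E18.5 both lists were higher, with medians of 0.06 (16 of 20 above 0) for the striatal and 0.09 (20 of 23) for the GABAergic list. More ventral forebrain stays open.

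The third pattern is that called genes gather on chromosome 6, although Chd8 lies on chromosome 14. A passenger segment beside Chd8 cannot be told apart from none: 0 of 99 genes within 5 Mb were called at E14.5, where the share elsewhere is 1.23% (Fisher's exact test p = 0.636), so too few calls were to be had. Genes with an unadjusted p under 0.05 at E14.5 were 15.2% within 5 Mb against 11.6% elsewhere (Fisher's exact test p = 0.269) and 25% within 1 Mb (3 of 12, Fisher's exact test p = 0.155). At E18.5 they were 8 of 100 within 5 Mb (Fisher's exact test p = 0.394) and 0 of 12 within 1 Mb. A segment of chromosome 6 linked to the KI is a candidate explanation: in the separate E18.5 libraries, genes of chromosome 6 had an unadjusted p under 0.05 more often than others (odds ratio 1.496, Fisher's exact test p = 0.008141, leaving out Setd5, Thumpd3 and Marchf8, whose values had been seen). The labels do not give the place of the added copy, and a segment within 5 Mb of Gt(ROSA)26Sor, a usual site of insertions on chromosome 6, cannot be told apart from the rest of the chromosome (odds ratio 1.979, Fisher's exact test p = 0.09139, at E18.5 without the same 3 genes), since 9 of 62 genes are too few to decide. With these 3 genes, whose values had drawn attention to the site, 11 of 65 genes had an unadjusted p under 0.05 at E18.5 (odds ratio 2.374, Fisher's exact test p = 0.0213; p = 0.136 within 10 Mb). At E14.5 it was 26 of 105 within 10 Mb (odds ratio 1.792, Fisher's exact test p = 0.0322, and p = 0.0732 within 5 Mb). Without the same 3 genes it was 13 of 59 within 5 Mb at E14.5 (odds ratio 1.474, Fisher's exact test p = 0.270). Within 1 Mb, with all genes, Fisher's exact test gave p = 0.198 at E14.5 and p = 0.729 at E18.5. In the authors' deposited tables, E14.5 then E18.5, the log2 fold changes there, chosen after the values were seen, were −0.35 and −0.43 for Gt(ROSA)26Sor (SE 0.110 and 0.121), −0.23 and −0.25 for Ift122 (SE 0.058 and 0.061), −0.11 and −0.15 for Setd5 (SE 0.043 and 0.038) and 0.23 and 0.21 for Marchf8 (SE 0.041 and 0.039). Effects of a different strain's alleles on chromosome 6 and effects of CHD8 itself on these genes were not separated.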

How the results depend on the processing

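The tests on genes called at E14.5 alone, and those leaving out chromosome 6 or, for lists, Chd8, were chosen only after the result was seen. The alternative tool, normalization, low-count filter, pseudocount, replicate block and left-out libraries, for gene counts and for Chd8, were not run because the tables used here hold no values per library. No paired analysis was possible because the tables used here hold no column per sample. For the same reason no other splits of the samples were counted and no library was compared with the rest of its group.

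At E14.5 the count of 162 became 56 with the Benjamini-Yekutieli adjustment, 31 with the empirical null, 319 and 74 at an adjusted p under 0.1 and 0.01, and 19 with an absolute log2 fold change of at least 0.5. It stayed within 1.5 times, at 139, 153 and 165, when adjusted over every gene with a p or over mean normalized counts of at least 10 or 100. The share of higher genes was 61.11% in the 162 and between 58.31% and 80.65% over these settings. At E18.5 the count of 9 became 14 at a mean normalized count of at least 100, 4 with Benjamini-Yekutieli, 19 with the empirical null, 18 at an adjusted p under 0.1 and 2 with the fold threshold. The stricter and looser thresholds act by construction, and the empirical null by the scale of the Wald statistics, 1.22 at E14.5 and 0.949 at E18.5. Of 214 results for single named genes, 31 lost their call with Benjamini-Yekutieli, 32 with the empirical null, 5 when adjusted over every gene (Atf4, Ldb2, Rims2, Ttyh1 and Wdpcp) and 1 at a mean normalized count of at least 10 (Ttyh1).

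The count of 12 lists past the test at E14.5 became 5 with a correlation of 0.05, 12 with ranks, 9 with log2 fold changes, 11 at a mean normalized count of at least 50 and 11 without Chd8 and chromosome 6. With log2 fold changes as the statistic the adjusted p at E14.5 was 0.289 for G2/M genes, 0.387 for radial glia, 0.376 for pan-neuronal genes, 0.0967 for the GABAergic lineage and 0.344 for cytosolic ribosomal proteins, while p53 targets and diencephalon markers passed (0.0182 and 0.0426). Ranks added ribosome biogenesis (adjusted p = 0.0343) and lost radial glia (0.0588). The count of 18 lists at E18.5 became 10 with a correlation of 0.05, 9 with log2 fold changes, 13 with ranks, 14 at a mean normalized count of at least 50 (where the diencephalon list had under 5 members), 17 without Chd8 and 15 without Chd8 and chromosome 6. With ranks the adjusted p at E18.5 was 0.253 for the CHD family, 0.127 for Cajal-Retzius cells, 0.0775 for REST targets, 0.0629 for the oligodendrocyte lineage and 0.0535 for mitochondrial respiration. With log2 fold changes it was 0.332 for pan-neuronal genes, upper-layer neurons, mitochondrial respiration and ribosome biogenesis, 0.402 for REST targets, 0.379 for synaptic vesicle genes, 0.140 for the CHD family, 0.126 for radial glia, 0.0963 for striatal neurons and 0.0553 for cytosolic ribosomal proteins, while microglia markers passed (0.0115). The cause of these changes with the statistic was not tested.

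The stage difference gave 0 genes in all but 1 setting: when adjusted over the 157 genes called at E14.5 and tested at both stages, 38 passed, which picks genes by their E14.5 value and so favours a difference. The correlation of the KI effect between stages, 0.215, became 0.305 at a mean normalized count of at least 100, 0.690 over the genes called at either stage, 0.2985 with Wald statistics, 0.213 without Chd8 and 0.204 without Chd8 and chromosome 6. The count of called genes beside Chd8 was 0 at 1, 5 and 10 Mb. No result changed direction while called. With the deposited SEs, changes of 0.15 log2 were recovered in 17.1% of simulated cases at E14.5, so small changes of single genes are largely missed.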

Other observations

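The imprinted list, the genes named here and the tests of this part were all chosen only after the result was seen.

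Imprinted genes, expressed from the copy of 1 parent, were higher in KI at both stages. A list of 51 imprinted genes was written after the called genes were known, and its p-values are adjusted over the 2 stages alone, so they do not compare with those of the 39 lists. At E14.5, 33 of 42 measured members were above 0 (median 0.10), 5 rose over all genes and 12 adjusted over the list alone (cameraPR adjusted p = 2.51e-08; adjusted p = 0.000214 with a correlation of 0.05), a test that includes the 5 genes that prompted the list. In the authors' deposited table Asb4 stood at 0.36 (SE 0.074), Dlk1 at 0.31 (SE 0.083), Peg3 at 0.31 (SE 0.062), Rian at 0.21 (SE 0.041) and Nnat at 0.11 (SE 0.031). Without these 5 genes, which had prompted the list, 28 of 37 were above 0 (adjusted p = 0.000367; adjusted p = 0.0172 with a correlation of 0.05). At E18.5, 33 of 41 members were above 0 (median 0.07, adjusted p = 1.14e-05; adjusted p = 0.00270 with a correlation of 0.05), with no member past over all genes and 2 past adjusted over the list alone. The 36 members other than those 5 had a median of 0.06 at E18.5 (adjusted p = 0.000675; adjusted p = 0.0172 with a correlation of 0.05).

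The genes of this paragraph were picked from the 162 called at E14.5 after their values were seen, and no theme shared by them was tested. In the authors' deposited table the axon guidance genes Draxin and Chl1 fell (−0.28, SE 0.049 and −0.31, SE 0.059), as did the transcriptional regulators Mef2c (−0.23, SE 0.047) and Id2 (−0.26, SE 0.058). Hmga2, a chromatin protein of young progenitors (0.43, SE 0.096), the DNA methyltransferase gene Dnmt3a (0.26, SE 0.048), the growth factor gene Mdk (0.25, SE 0.046) and Notch3 (0.20, SE 0.051) rose in the authors' deposited table. Genes with a mean normalized count under 50 gave the changes of more than 1 log2 unit: Hebp1 at 1.20 (SE 0.262) and Sspn at −1.09 (SE 0.241) in the authors' deposited table. Hebp1, Sspn and Chl1 lie on chromosome 6, where called genes gather.

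At E18.5, 85 genes of the authors' deposited table have no p-value, against 3 at E14.5. Of the 33 genes of the meninges and choroid plexus lists in the table, 17 are among them, against 0.441% of other genes (Fisher's exact test p = 7.69e-31), while at E14.5 none of 33 is. The test treats genes as independent, and markers of the same tissue can vary together, so this p overstates the evidence. In the authors' deposited table the most abundant of the 85 are Ttr (mean normalized count 2718, log2 fold change 0.27, SE 1.88), Igf2 (1799, 0.08, SE 0.730), H19 (1011, 0.20, SE 0.623) and Ptgds (563, 0.66, SE 1.69). The SEs of the members of both lists had a median of 0.745 at E18.5 and 0.387 at E14.5. DESeq2 by default leaves the p empty where a single library has an extreme count, and whether that setting was used is not recorded in the header.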
